A study of Homo sapiens with 10 samples.

How the data were processed

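Gene expression was measured with 10 one-colour Affymetrix arrays, 1 for each culture condition. HCT116 is a colorectal carcinoma cell line and Hke3 a line derived from it, and each was profiled in 4 conditions: alone, with vitamin D3, with THP1 macrophages, and with both. THP1, a monocytic leukaemia line, was profiled alone and with vitamin D3. Vitamin D3 treatment lasted 24 hours. The authors deposited log2 intensities per probe set made with RMA, which corrects background, quantile-normalises and summarises probes, through the R package affy, with no version stated. Whether the authors normalised the 10 arrays together is not stated. All deposited log2 values lay between 2.98 and 15.2, with array medians from 6.15 to 6.21.

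Arrays were grouped by their titles. For the Hke3 array titled as treated with vitamin D3, 1 label field calls the cells untreated, while the title, the description and the culture field give vitamin D3; it was kept as treated. Of 54675 probe sets, 41097 map to 1 gene symbol and 1801 map to several, and the latter were left out. Each of the 19775 genes was represented by its probe set with the highest mean. A gene was tested where its highest value over the 8 colon cancer arrays exceeded 6.18 log2, the median of all values, which left 13243 genes, and the same threshold over both THP1 arrays left 12717 genes. Arrays give no counts, so their number limits the precision. Of the genes that the naming rule always takes, 2 are not analysed here.

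The 8 colon cancer arrays were fitted with limma 3.58.1 in R 4.3.3, with cell line, coculture and vitamin D3 as additive terms and 4 residual degrees of freedom. No paired analysis of replicates was possible because each condition has 1 array, so the 4 pairs of arrays that differ in 1 factor take the place of replicates. The error is how far a difference varies between them, pooled with the interaction of the other 2 factors. A block of the other 2 factors, among the alternatives below, takes that interaction out and leaves 3 residual degrees of freedom. Each interaction was added to this model on its own, with 3 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Values after ± are standard errors of the fit unless called SD. The THP1 pair has no residual degrees of freedom, so its differences carry no test.

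Before the data were examined, 22 gene lists, the rule for naming genes and the alternatives were fixed. The lists are vitamin D receptor targets, NF-kB and IL-1 response, interferon response, Wnt and beta-catenin targets, mesenchymal genes, epithelial genes, hypoxia and glycolysis, cholesterol synthesis, ATF4 amino acid response, ER chaperones, mitosis, DNA replication, p53 targets, RAS-MAPK output, immediate early genes, NRF2 targets, metallothioneins, heat shock, death receptor signalling, macrophage markers, myeloid surface receptors and macrophage cytokines. Lists were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance 1 way without comparing them with other genes, was run beside it. Member counts are given over all genes tested and adjusted over the list alone. For THP1, a list's median was placed among 10000 random lists of the same size drawn from 10 bins of mean expression.

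The rule names, for coculture, vitamin D3 and cell line, the 10 largest rises and 10 largest falls among genes past the threshold with 1 sign in all 4 pairs. With fewer than 5 genes past the threshold in a direction, it names the 5 with the smallest p there, as values. It names the 5 largest interactions of each sign past the threshold, or with none past it the 3 with the smallest p. It takes 12 differences of each sign in THP1, and up to 4 members per list, past the threshold first. VDR, CYP24A1, SNAI1, AXIN2 and IL1B are always named.

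Alternatives were no filter on dim genes, a filter at the 75th percentile (8.15 log2), the mean of a gene's probe sets, each probe set on its own, median-centred arrays, cyclic loess normalisation, eBayes with trend and robust fitting, leaving out each array, a block of the other 2 factors, a minimum of 1.5-fold, all two-way interactions together, and subsets of arrays. A model without the vitamin D3 labels was added after the data were seen. The model, camera and the random lists were checked on simulated data with the real means and residual spreads. For the model, each simulated set held 200 changed genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.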

Results

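The arrays compare 2 related colon cancer lines with and without coculture with THP1 macrophages and with and without vitamin D3, whose hormone form activates the vitamin D receptor. HCT116 and Hke3 were grown with THP1 cells in a setting where the cells did not touch but shared medium. There are 8 colon cancer arrays and 2 THP1 arrays, and no condition has replicates. The ACTB probe sets, whose 3' minus 5' difference rises as RNA quality falls, gave 0.24 ± 0.06 log2 (SD, n = 4) in HCT116, 0.71 ± 0.17 (SD, n = 4) in Hke3 and 0.04 ± 0.08 (SD, n = 2) in THP1. The 4 Hke3 values were 0.94 alone, 0.72 with vitamin D3, 0.62 in coculture and 0.56 with both. The same difference for the GAPDH probe sets was -0.097 ± 0.002 log2 (SD, n = 4) in HCT116, 0.03 ± 0.027 (SD, n = 4) in Hke3 and -0.106 ± 0.001 (SD, n = 2) in THP1.

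Across the 2 colon cancer lines, 15 of 18 DNA replication genes and 15 of 20 mitosis genes fell with coculture, and 6 of 19 hypoxia and glycolysis genes rose. The calls of these 3 lists by camera were lost with an estimated correlation (adjusted p = 0.164, 0.164 and 0.322). Among genes past the threshold with 1 sign in all 4 pairs, the largest rise was that of NDRG1, a hypoxia-induced gene. It rose 2.60-fold (log2 difference 1.38 ± 0.20, adjusted p = 0.014, higher in 4 of 4 pairs). Next came IGFBP3, which binds insulin-like growth factors (log2 1.24 ± 0.27, an approximate size because its mean without coculture lay under 6.18 log2, as for IFIH1 and HLA-DRA below), ARRDC4, an arrestin-related glucose-responsive gene (2.30-fold), LOXL2, which crosslinks collagen (1.19 ± 0.16), and ALDOC, a glycolytic aldolase (1.10 ± 0.22). ADGRF1, an adhesion G protein-coupled receptor, rose by 1.05 ± 0.09 and had the smallest adjusted p, 0.00731. KRT15, a keratin, rose by 1.004, CLIC3, an intracellular chloride channel, by 0.91, PLAUR, the urokinase receptor, by 0.91, and P4HA1, a collagen prolyl hydroxylase subunit, by 0.91. The largest falls among such genes were in HIRA, a histone chaperone (log2 -1.03 ± 0.23), HSPH1, a heat shock chaperone (-0.65 ± 0.06), KRT7, a keratin (-0.64 ± 0.07), RCC1, the exchange factor for the RAN GTPase (-0.63 ± 0.08), and HELLS, a chromatin remodeller (-0.62 ± 0.09). APH1A, a subunit of gamma-secretase, fell by 0.60, the RNA-binding gene UNK by 0.59, METRN by 0.58, the cell polarity gene PRICKLE1 by 0.57 and the zinc finger gene ZNF738 by 0.56. In all, limma called 1035 of 13243 genes, 498 higher and 537 lower, and 1033 of them had 1 sign in all 4 pairs. Most differences were small, since 7 of the higher genes and 1 of the lower exceeded 2-fold.

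Of 18 DNA replication genes tested, 15 fell with coculture, 18 when adjusted over the list alone (camera adjusted p = 5.65e-13; adjusted p = 0.164 with an estimated correlation). GINS2 fell by 0.52, MCM5 by 0.48, UHRF1 by 0.47 and FEN1 by 0.44 on the log2 scale. Of 20 mitosis genes 15 fell, 17 when adjusted over the list alone (camera adjusted p = 3.33e-11; adjusted p = 0.164 with an estimated correlation), among them the kinases PLK1 (log2 -0.47) and AURKA (-0.36), the motor KIF11 (-0.43) and the anaphase activator CDC20 (-0.36). All 18 replication genes lay below 0 in HCT116 and in Hke3, and 19 of 20 mitosis genes did so in each line. Of 7 heat shock genes 3 fell, HSPH1, HSPE1 (log2 -0.44) and DNAJB1 (-0.29), and 5 when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.322 with an estimated correlation). Of 19 hypoxia and glycolysis genes 6 rose and 17 did so when adjusted over the list alone (camera adjusted p = 1.12e-10; adjusted p = 0.322 with an estimated correlation); NDRG1, ALDOC, P4HA1 and PDK1, a kinase that restrains pyruvate oxidation (log2 0.84), were among the 6.

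A further 7 lists passed by camera for coculture with 1 to 3 members past the threshold. Of 19 interferon response genes 3 rose, IRF7 (log2 0.69), IRF9 (0.52) and the RNA sensor IFIH1 (0.49), and 5 when adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.164 with an estimated correlation). Of 13 immediate early genes 2 rose, KLF4 (0.63) and JUN (0.51), and 9 when adjusted over the list alone (camera adjusted p = 3.4e-06; adjusted p = 0.312 with an estimated correlation). Of 21 RAS-MAPK output genes 3 rose, the growth factor TGFA (0.42), the phosphatase DUSP5 (0.41) and IER3 (0.38), and 7 when adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.438 with an estimated correlation). Of 9 NRF2 targets GCLC, which makes glutathione, rose (0.57), and 4 when adjusted over the list alone (camera adjusted p = 0.0005; adjusted p = 0.171 with an estimated correlation). Of 12 vitamin D receptor targets IGFBP3 and CLMN (0.26) rose, and 4 when adjusted over the list alone (camera adjusted p = 0.00953; adjusted p = 0.22 with an estimated correlation). Of 13 epithelial genes the transcription factor ELF3 rose (0.53), and 3 when adjusted over the list alone (camera adjusted p = 0.0219; adjusted p = 0.316 with an estimated correlation). Of 8 macrophage cytokine genes the chemokine CXCL8 rose (0.76), and 2 when adjusted over the list alone (camera adjusted p = 0.0455; adjusted p = 0.286 with an estimated correlation). NF-kB and IL-1 response genes as a list missed the threshold (camera adjusted p = 0.0777), with CXCL8, IER3 and NFKB2 (0.32) higher among 19. The p53 targets (camera adjusted p = 0.0777) held TP53INP1, which rose by 0.30 (another of its bright probe sets pointed the other way), PLK3, which rose by 0.23, and AEN, which fell by 0.24; death receptor genes (0.21) held TNFRSF10D (0.53) and BIRC2 (0.22), both higher, and ER chaperones (0.246) held SDF2L1, which fell by 0.56, and CALR, which fell by 0.24. Of the lists that passed by camera for coculture, fry passed replication and mitosis (adjusted p = 0.00457 for both), interferon response (0.0142), NRF2 targets (0.0178), heat shock (0.0282) and macrophage cytokines (0.0448), and not hypoxia and glycolysis (0.0814), immediate early genes (0.078), RAS-MAPK output (0.172), vitamin D receptor targets (0.0658) or epithelial genes (0.0728).

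Markers of the macrophages stayed low in the cocultured cancer cells. SRGN, the brightest marker in THP1 at 13.97 log2, had a mean of 4.30 log2 without coculture and 4.99 with it, and its difference of 0.69 missed the threshold (adjusted p = 0.139). Its 4 pairs gave 0.49 and 0.20 in HCT116 and 0.18 and 1.90 in Hke3, the last from the Hke3 array in coculture with vitamin D3, which also had the highest median of the 16 markers among the colon cancer arrays, 5.69 log2 (5.39 to 5.54 on the others, 11.58 and 11.71 in THP1). LAPTM5 differed by 0.01 and ITGB2 by -0.19. HLA-DRA, an MHC class II chain, rose by 0.46 (adjusted p = 0.0481), and the list as a whole had a camera adjusted p of 0.662, with 1 of 7 tested genes past the threshold. Wnt and beta-catenin targets (camera adjusted p = 0.948), mesenchymal genes (0.361), cholesterol synthesis (0.0777), ATF4 amino acid response (0.246), metallothioneins (0.451) and myeloid surface receptors (0.948) had no member past the threshold. The always-named genes VDR (log2 0.04), CYP24A1 (-0.29), SNAI1 (0.04), AXIN2 (-0.05) and IL1B (-0.11) did not pass for coculture.

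The coculture count was 39 without the HCT116 array with vitamin D3, 176 without HCT116 in coculture with vitamin D3, 306 without Hke3 alone, 309 without HCT116 in coculture, 348 without Hke3 in coculture, 365 without HCT116 alone, 395 without Hke3 with vitamin D3 and 435 without Hke3 in coculture with vitamin D3. It was 656 with no filter on dim genes, 259 with a block of the other 2 factors and 75 at a minimum of 1.5-fold, and cyclic loess normalisation changed the balance to 632 higher and 448 lower.

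The lines differed in how coculture changed them: 12 of 19 hypoxia and glycolysis genes and 7 of 15 cholesterol synthesis genes had the larger value in Hke3, and 10 of 15 ATF4 amino acid response genes had it in HCT116. The calls of these 3 lists by camera were lost with an estimated correlation (adjusted p = 0.482, 0.23 and 0.11). The interaction passed for 557 genes, 247 with the larger value in Hke3 and 310 with the larger value in HCT116, and for 426 of them the mean differences of the lines had opposite signs. A larger value is the higher signed difference, so it can come from a rise in that line or a fall in the other. ANKRD37, a hypoxia-induced gene, differed by 2.45 log2 in Hke3 and 0.33 in HCT116 (interaction 2.12 ± 0.27, adjusted p = 0.0113). PFKFB4, which regulates glycolysis, differed by 1.63 and -0.12, ANGPTL4, an inhibitor of lipoprotein lipase, by 1.99 and 0.25, SPRY1, an inhibitor of receptor tyrosine kinase signalling, by 1.24 and -0.29, and PPFIA4, a liprin, by 1.41 and -0.04, in Hke3 and HCT116. In the other direction stood the cytokine receptor chain IL20RB (-0.75 in Hke3 and 1.62 in HCT116), the ER chaperone CLGN (0.05 and 2.21), LURAP1L (-0.11 and 2.01), the lysosomal protein LAMP3 (0.21 and 2.23) and the semaphorin and VEGF receptor NRP1 (0.37 and 2.38). CLGN had the smallest adjusted p, 0.00164. VDR (-0.18), CYP24A1 (0.47), SNAI1 (-0.09), AXIN2 (0.11) and IL1B (0.14) did not pass.

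Of 19 hypoxia and glycolysis genes, 12 had the larger value in Hke3, 17 when adjusted over the list alone (camera adjusted p = 2.91e-13; adjusted p = 0.482 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, was one of them (interaction 1.40). The list's median coculture difference was -0.04 log2 in the HCT116 pair without vitamin D3, 0.40 in the HCT116 pair with it, 1.11 in the Hke3 pair without it and 1.57 in the Hke3 pair with it. Between the same Hke3 arrays the ACTB 3' minus 5' difference was lower with coculture, by a mean of -0.24. Of 15 cholesterol synthesis genes 7 had the larger value in Hke3, 9 when adjusted over the list alone, among them INSIG1, which restrains sterol synthesis (-0.43 in HCT116 and 0.84 in Hke3), and the sterol carrier STARD4 (0.05 and 1.045). The list's median was -0.095 in HCT116 and 0.31 in Hke3 (camera adjusted p = 2.24e-08; adjusted p = 0.23 with an estimated correlation). Of 15 ATF4 amino acid response genes 10 had the larger value in HCT116, 13 when adjusted over the list alone (camera adjusted p = 1.7e-16, and 0.11 with an estimated correlation). The list's median was 0.31 in HCT116, with 13 of 15 genes above 0, and -0.40 in Hke3, with 11 of 15 below 0. SESN2, an inhibitor of mTORC1, differed by 1.14 log2 in HCT116 and -0.55 in Hke3, DDIT3, a stress-induced transcription factor, by 1.77 and 0.09, CHAC1, which degrades glutathione, by 1.08 and -0.51, and the pseudokinase TRIB3 by 1.09 and -0.46.

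Members of the ER chaperone and p53 lists past the threshold had the larger value in HCT116. The ER chaperone list had a camera adjusted p of 0.000729, and 0.437 with an estimated correlation. Of its 12 genes 4 had the larger value in HCT116, 5 when adjusted over the list alone, including HYOU1 (interaction -0.79), HERPUD1 (-0.78) and SEL1L (-0.72). Of 16 p53 targets 4 did so, 5 when adjusted over the list alone, including the cytokine GDF15 (-0.99), the TRAIL receptor TNFRSF10B (-0.78) and the cell cycle inhibitor CDKN1A (-0.65; camera adjusted p = 2.97e-05; adjusted p = 0.181 with an estimated correlation). The cystine transporter SLC7A11 (-0.97), the ERK phosphatase DUSP6 (-0.76), the transcription factors TWIST1 (-0.98) and SOX9 (-0.51), and the splicing factor ESRP1 (-0.57) also had the larger value in HCT116, and the Wnt inhibitor DKK1 (1.26) in Hke3. The size for TWIST1 is approximate, because its mean in Hke3 lay under 6.18 log2. RAS-MAPK output (camera adjusted p = 0.0342; adjusted p = 0.772 with an estimated correlation), immediate early genes (0.0393; adjusted p = 0.772 with an estimated correlation) and heat shock genes (0.0361; adjusted p = 0.437 with an estimated correlation) passed by camera with 1, 0 and 0 members past the threshold, the first 2 with medians of -0.07 and -0.32, toward HCT116, and heat shock with 0.16, toward Hke3. Of the lists that passed by camera for this interaction, fry passed ATF4 amino acid response (adjusted p = 0.00162), p53 targets (0.00137), cholesterol synthesis and heat shock (0.0178 for both) and ER chaperones (0.0213), and not hypoxia and glycolysis (0.0721), RAS-MAPK output (0.443) or immediate early genes (0.588). The count of 557 was 105 without HCT116 alone, 148 without HCT116 with vitamin D3, 129 without HCT116 in coculture, 112 without HCT116 in coculture with vitamin D3, 130 without Hke3 alone, 101 without Hke3 with vitamin D3, 282 without Hke3 in coculture and 185 without Hke3 in coculture with vitamin D3. It was 277 with no filter on dim genes, 973 with the filter at the 75th percentile, 865 for each probe set on its own and 1169 with trend and robust fitting.

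**Figure D1:**
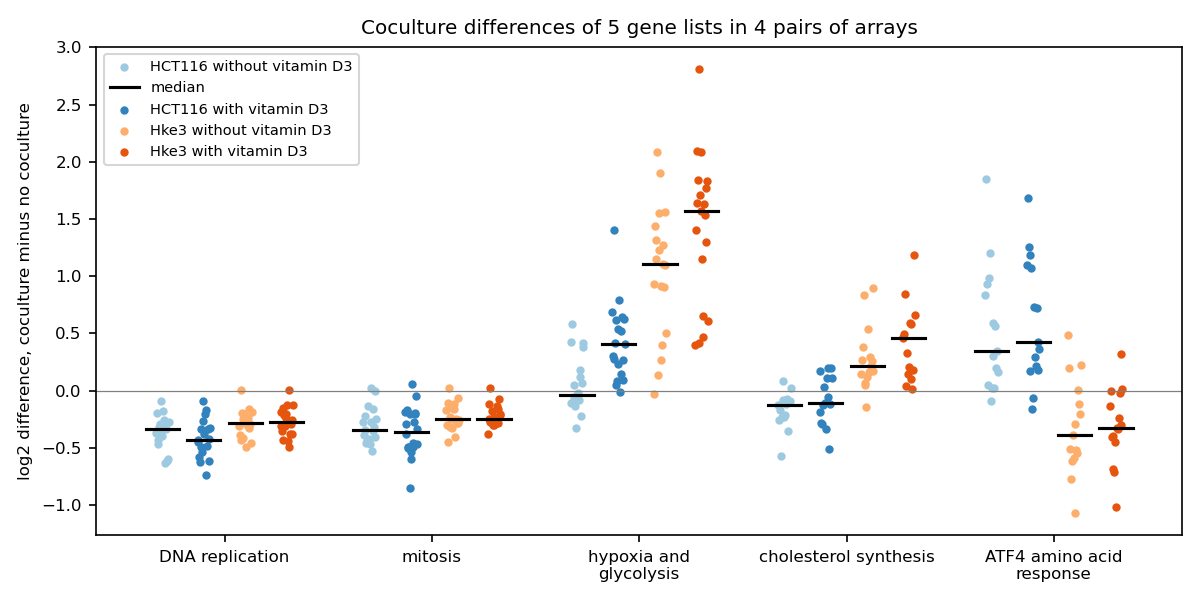
Each point is 1 gene of a list (5 lists, horizontal axis) in 1 of 4 pairs of arrays, the vertical axis is the log2 difference of coculture minus no coculture, and black bars are medians. Replication and mitosis medians lie below 0 in all 4 pairs, while the hypoxia median runs from -0.04 and 0.40 in HCT116 to 1.11 and 1.57 in Hke3.

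Across all tested genes, the mean coculture difference of HCT116 and that of Hke3 correlated weakly (Pearson r = 0.279, Spearman rho = 0.28, across genes, which are not independent replicates). The 100 genes most raised in Hke3 had a median in HCT116 of 0.07 log2 without vitamin D3 and 0.36 with it, and the 100 most lowered had -0.08 and -0.025. The 100 genes most raised in HCT116 had a median in Hke3 of 0.12 without vitamin D3 and 0.13 with it, and the 100 most lowered had -0.24 and -0.20. These medians carry no test. The division of coculture values by vitamin D3, here and for the hypoxia list, rests on the deposited labels, which the signs of CYP24A1 below put in doubt; a mean of both pairs of a line does not depend on them.

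The cell lines differed in 5364 genes, 3287 higher and 2077 lower in Hke3, of which 151 and 65 exceeded 2-fold. The matricellular gene CCN2 was 13.7-fold higher in Hke3 (log2 3.78 ± 0.15, adjusted p = 3.37e-06, 4 of 4 pairs), and its relative CCN1 was 4.30-fold higher. The homeobox gene HOXB8 (log2 3.43 ± 0.08), the immediate early factor EGR3 (2.66 ± 0.23), the chemokine CXCL8 (2.45 ± 0.16), the hexokinase-related HKDC1 (2.37 ± 0.31), IGFBP3 (2.33 ± 0.27), SYTL2, which acts in vesicle traffic (2.32 ± 0.25), the lysosomal protease CTSZ (2.30 ± 0.11) and the kinase DCLK1 (2.30 ± 0.22) were also higher in Hke3; another bright probe set of CTSZ pointed the other way. Higher in HCT116 were the annexin ANXA10 (-3.46 ± 0.10), the cAMP phosphodiesterase PDE4B (-3.12 ± 0.07), FCF1 (-3.06 ± 0.16), the vasoactive peptide gene UTS2 (-2.87 ± 0.12) and the calcium sensor VSNL1 (-2.84 ± 0.07). KCTD12 (-2.61), the protein kinase A subunit PRKACB (-2.50), the noncoding RNA VHRT (-2.49), SUN3 (-2.27) and the splicing regulator MBNL3 (-2.25) followed. For EGR3, CXCL8, IGFBP3, FCF1, UTS2, KCTD12, VHRT, SUN3 and MBNL3, and for SPP1, IFIH1 and TWIST1 below, the mean of the dimmer line lay under 6.18 log2. The size and the rank of these differences are therefore approximate. Their dimmer level was not set to 6.18 log2, as it was for THP1 below, so they are not lower bounds and may be too large.

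Of 21 RAS-MAPK output genes 14 were higher and 2 lower in Hke3, the same counts as when adjusted over the list alone; DUSP4 (log2 1.14), the cyclin CCND1 (1.11), the cytokine LIF (1.05) and the AP-1 gene FOSL1 (0.89) were among the higher. Of 13 immediate early genes 11 were higher and 1 lower, also when adjusted over the list alone, with FOSB (1.56), NR4A1 (1.41) and KLF6 (1.21) beside EGR3. Both lists had a camera adjusted p of 0.00306, an adjusted p = 0.695 with an estimated correlation and a fry adjusted p of 0.011. No other list passed by camera. Fry also passed Wnt and beta-catenin targets (adjusted p = 0.00333), interferon response (0.0048) and myeloid surface receptors (0.0118). It passed NF-kB and IL-1 response, vitamin D receptor targets and macrophage cytokines as well (0.00557 for each). Wnt and beta-catenin targets had 9 of 15 higher and 2 lower, with DKK1 (1.26), SOX9 (1.17) and the feedback inhibitor AXIN2 (0.82) higher (camera adjusted p = 0.115), although 2 other bright probe sets of AXIN2 pointed the other way. NF-kB genes had 8 of 19 higher and 2 lower, including TNFAIP3 (1.36), NFKBIA (0.96) and TNFAIP2 (0.91; camera adjusted p = 0.246). Interferon response genes had 11 of 19 higher and 2 lower, with HERC6 (0.76) and IFIT1 (0.74) higher and IFIH1 (-0.80) lower (camera adjusted p = 0.11). DNA replication genes had 2 of 18 higher and 7 lower, SLBP (-0.48) and CDC6 (-0.46) among them (camera adjusted p = 0.115). Among hypoxia and glycolysis genes, 4 higher and 3 lower of 19, the glucose transporter SLC2A1 was lower (-2.12) and the enolase ENO2 higher (1.71). Single genes past the threshold included the vitamin D receptor targets SPP1 (1.90) and KLK6 (1.56), the mesenchymal genes FN1 (1.40, with 1 of 5 bright probe sets pointing the other way), VIM (0.58) and TWIST1 (-1.32), the keratin KRT8 (0.65), the heat shock genes HSPB1 (0.57) and HSPH1 (-0.87), and CTH, which makes cysteine (-0.63). CYP24A1 (1.14, adjusted p = 0.0836), VDR (-0.05), SNAI1 (0.02) and IL1B (-0.08) did not pass. The ACTB 3' minus 5' difference separates the lines completely. The GAPDH difference does too, but its means lay nearer together, at -0.097 in HCT116 and 0.03 in Hke3. RNA quality and cell line therefore cannot be told apart here. The median of all genes was 0.01 higher in Hke3 and -0.09 with median-centred arrays, which called 2234 genes higher and 4094 lower, and a minimum of 1.5-fold left 938.

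No gene passed for vitamin D3 in the colon cancer cells. Limma gave 0 genes, with 375 at an unadjusted p under 0.05 where chance gives 662. The error of this fit also holds the interaction of cell line and coculture, which raises it. With a block of the other 2 factors, which takes that interaction out, 704 genes had an unadjusted p under 0.05 and 0 passed. In the 4 pairs 1, 0, 7 and 5 genes exceeded 2-fold. On simulated arrays with 200 changed genes, the model recovered 98% of 1.5-fold and 30% of 1.2-fold changes that had 1 sign in all 4 pairs. With few changed genes the adjustment is stricter, so recovery would be lower and the count of 0 does not rule out single changes of this size. A response of opposite signs with and without coculture, as for CYP24A1 below, cancels in the vitamin D3 count. It falls to the interaction of coculture and vitamin D3, where 32% of 1.5-fold and 90% of 2-fold interactions were recovered. For a response of opposite signs the interaction is larger than the change with or without coculture. The 5 smallest p-values for higher genes belonged to AOC3 (log2 0.28), the chemokine CXCL1 (0.28), the arginine sensor CASTOR1 (0.24), CSTF2T (0.25) and TMEM171 (0.22), all with an adjusted p of 1. Those for lower genes belonged to the adenylyl cyclase ADCY5 (-0.33), ZYG11A (-0.32), GPRASP3 (-0.23), the Notch target HEYL (-0.25) and PGM5-AS1 (-0.34), with an adjusted p of 1. VDR (0.07), CYP24A1 (0.14), SNAI1 (-0.06), AXIN2 (-0.07) and IL1B (-0.09) did not pass. Of the lists, immediate early genes passed by camera (median 0.10, adjusted p = 0.00891; adjusted p = 0.857 with an estimated correlation; fry adjusted p = 0.948) with 0 of 13 members past the threshold. The vitamin D receptor targets had 0 of 12 members past it (camera adjusted p = 0.529).

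CYP24A1, which encodes the enzyme that breaks down the vitamin D hormone and is its classic target, went opposite ways with and without macrophages. The arrays labelled vitamin D3 had 1.44 log2 more CYP24A1 in HCT116 alone and 1.45 more in Hke3 alone, but with coculture they had -0.98 in HCT116 and -1.36 in Hke3. In Hke3 its level was 10.89 alone, 12.35 with vitamin D3, 12.25 in coculture and 10.89 with both, and in HCT116 it was 9.99, 11.43, 10.68 and 9.70. FN1, fibronectin, followed the same order of signs (0.70 and 0.95 without coculture, -0.70 and -1.001 with it), and GDA, guanine deaminase, the opposite one (-0.35 and -0.51 without, 0.52 and 0.54 with). These 3 had the smallest p for the interaction of coculture and vitamin D3: CYP24A1 -2.62 ± 0.23 (adjusted p = 0.122), FN1 -1.68 ± 0.18 (adjusted p = 0.194) and GDA 0.96 ± 0.11 (adjusted p = 0.194). Limma called 0 genes, with 652 at an unadjusted p under 0.05. The error of this fit holds the interaction of cell line and coculture. With all two-way interactions together, which leaves 1 residual degree of freedom, 10 genes passed and 1488 had an unadjusted p under 0.05. On simulated arrays with 200 changed genes the model with this 1 interaction recovered 90% of 2-fold interactions. With few changed genes the adjustment is stricter, and CYP24A1 missed the threshold at -2.62. The count of 0 therefore does not show that 2-fold changes were absent. VDR (0.17), SNAI1 (-0.20), AXIN2 (-0.05) and IL1B (-0.14) did not pass. CYP24A1 alone passed for vitamin D3 when only the arrays without coculture were fitted (log2 1.45, adjusted p = 0.00178). For the interaction it passed with the mean of probe sets, with TM4SF18 (adjusted p = 0.0495 for both; TM4SF18 is named after its value was seen), and without the HCT116 coculture array (adjusted p = 0.0255).

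**Figure D2:**
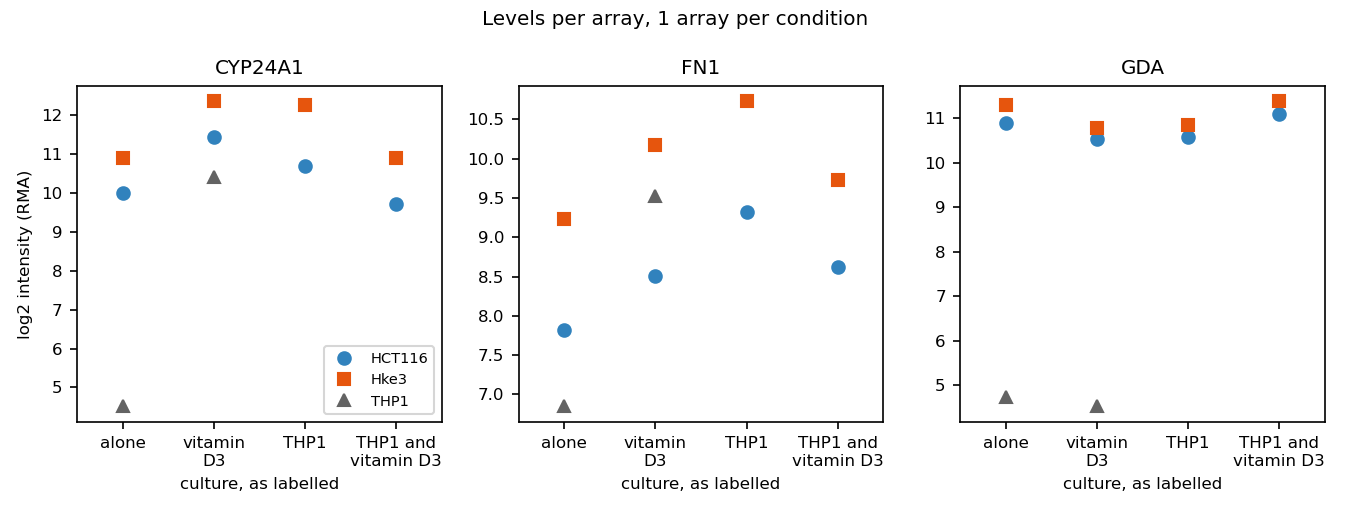
Points are log2 intensities (vertical axis) of CYP24A1, FN1 and GDA on single arrays, by culture condition as labelled (horizontal axis) and cell line. In HCT116 and in Hke3, CYP24A1 is higher with vitamin D3 than without it in cells alone and lower with vitamin D3 than without it in coculture.

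By camera, the interaction of coculture and vitamin D3 was positive for RAS-MAPK output (median 0.25, adjusted p = 0.00017; adjusted p = 0.425 with an estimated correlation), hypoxia and glycolysis (0.36) and metallothioneins (0.22), and negative for vitamin D receptor targets (-0.06). These last 3 had an adjusted p of 0.0276 and an adjusted p = 0.853 with an estimated correlation. Macrophage markers also had a negative value (-0.16, adjusted p = 0.00819; adjusted p = 0.715 with an estimated correlation), and no list had a member past the threshold. None of the 5 passed by fry (adjusted p from 0.409 to 0.953). For a vitamin D3 effect that differs between the lines, the model recovered 22% of 1.5-fold and 92% of 2-fold changes on simulated arrays. These held 200 changed genes, and with few changed genes recovery would be lower. Limma gave 0 genes for this interaction, with 144 at an unadjusted p under 0.05. With all two-way interactions together it also gave 0, with 533 at an unadjusted p under 0.05. The smallest p-values there belonged to the chemokine CCL5 (-0.64), RASL11A (0.66) and ATXN7L3-AS1 (0.57), each with an adjusted p of 1. VDR (0.11), CYP24A1 (-0.18), SNAI1 (0.02), AXIN2 (0.09) and IL1B (0.15) did not pass either. Across genes the vitamin D3 differences of the lines correlated at r = 0.164 and rho = 0.166 as means of their 2 pairs, 0.089 and 0.057 in the pairs without coculture, and 0.278 and 0.279 in the pairs with it.

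In THP1 cells most vitamin D receptor targets were higher with vitamin D3, 12 of 17 by over 2-fold. These values compare 1 array with 1 array and carry no test. Where 1 of the 2 levels lay under 6.18 log2, it was set to that value, and the fold or difference is a lower bound with no rank. Among genes brighter than this on both arrays, FBP1, a gluconeogenic enzyme, was 45.0-fold higher, CD14, the coreceptor for bacterial lipopolysaccharide, 44.4-fold, CAMP, which encodes an antimicrobial peptide, 42.4-fold, and the neutrophil chemokine CXCL8 21.3-fold. The sulfotransferase SULT1C2 was at least 31.8-fold higher, CYP24A1 at least 18.7-fold, the acute phase gene ORM1 at least 15-fold, the chemokine CXCL1 at least 11.4-fold, RFPL2 at least 10.4-fold, TSPAN18 at least 9.78-fold, the myeloid receptor TREM1 at least 9.10-fold and CLMN at least 7.16-fold. Lower were the MHC class II genes HLA-DRA (log2 -2.85) and HLA-DPA1 (-2.31), the aldo-keto reductases AKR1C2 (-2.66) and AKR1C1 (-1.93), VAT1L (-2.44) and the transcription factor ONECUT2 (-2.32). The methyltransferase gene SMYD3 (-1.96), DEPTOR, an inhibitor of mTOR (-1.96), and the relaxin receptor RXFP1 (-1.87) were lower too, as were the chemokine CXCL14 (by at least 1.57), the noncoding RNA CCDC26 (by at least 0.69) and the transporter ABCA6 (by at least 0.29). Of 12717 genes, 260 exceeded 2-fold, 198 higher and 62 lower, and 225 did so as lower bounds, 174 higher and 51 lower. IL1B differed by 0.76 and VDR by -0.25. SNAI1 was lower by at least 0.03, and AXIN2 lay under 6.18 log2 on both arrays.

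**Figure D3:**
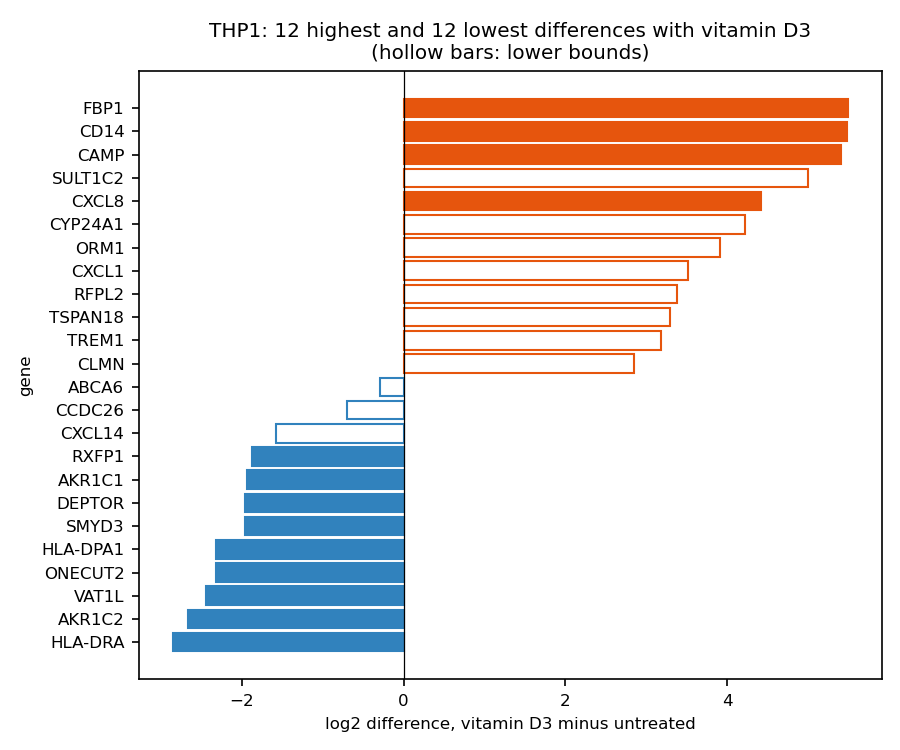
Bars are log2 differences (horizontal axis) of vitamin D3 minus untreated THP1 cells, 1 array each, for the 12 genes with the highest and the 12 with the lowest difference. Hollow bars are lower bounds, with the dimmer level set to 6.18 log2. Filled bars run from 5.49 for FBP1 to -2.85 for HLA-DRA.

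Of 17 vitamin D receptor targets present in THP1, 12 were over 2-fold higher, and their median of 2.62 log2 lay above all 10000 random lists. NF-kB and IL-1 response genes (median 0.53, 5 of 18 over 2-fold higher, CXCL2 at 2.28 or more and SOD2 at 1.16 among them), macrophage cytokines (0.43, 5 of 13 higher and 1 lower, CCL8 at 2.43) and interferon response genes (0.33, 1 of 27 higher, IFIT2 at 1.34) also had medians above all random lists. DNA replication (-0.36, with CDC6 at -0.75 and MCM2 at -0.54), ATF4 amino acid response (-0.27, ASNS at -1.05) and metallothioneins (-0.53, MT1X at -0.59 and MT2A at -0.54) had medians below all of them, and mitosis genes (-0.20) lay at percentile 0.03. Immediate early genes (median 0.30, KLF4 at 1.48, percentile 99.9) and death receptor genes (0.28, CFLAR at 0.57, percentile 99.9) lay high. Mesenchymal genes had -0.24 (percentile 0.99), but -0.034 with dim levels set to 6.18 log2, and FN1 was higher by 2.68. Macrophage markers had a median of 0.09 with LYZ higher (1.78) and HLA-DRA lower. Across 12081 genes the vitamin D3 difference of THP1 correlated with the mean of the 4 colon cancer pairs at r = 0.107 and rho = 0.119.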

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

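The tests of exchanged labels, macrophage RNA, RNA quality and culture conditions were chosen after the results were seen, and those of other splits of the arrays before their results were seen, except the splits with an interaction kept in the model.

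Among the named genes, the vitamin D3 differences of CYP24A1, FN1, GDA and SNAI1 had opposite signs with and without macrophages in both lines. Their interactions were -2.62, -1.68, 0.96 and -0.20, none past the threshold (limma adjusted p = 0.122, 0.194, 0.194 and 0.995). SNAI1 is listed for its signs alone. If the labels of vitamin D3 were exchanged between the coculture arrays of a line, genes raised by vitamin D3 in cells alone would be lower than genes it lowered in the coculture pair, which shares no array. The 20 most raised minus the 20 most lowered gave -0.8 in Hke3, where random lists gave -0.085 to 0.095 (5th to 95th percentile), and -0.262 in HCT116, where they gave -0.104 to 0.094. With 50 genes each way it was -0.497 in Hke3 (random lists -0.055 to 0.061) and a smaller -0.098 in HCT116 (-0.063 to 0.063), and across all genes the pairs with and without coculture correlated at r = -0.22 in Hke3 and -0.047 in HCT116. The values for 20 genes are what exchanged labels need, so these are a candidate explanation in each line, with weaker evidence in HCT116. The 20 genes most raised in THP1 did not turn from higher to lower in either line, with medians of -0.05 alone and 0.19 in coculture in HCT116, and 0.16 and 0.07 in Hke3, untested. A response turned by macrophages cannot be told apart from them, because it is the same contrast (smallest adjusted p 0.122), and the deposited labels were kept.

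For coculture, 12 of 19 hypoxia and glycolysis genes had the larger value in Hke3, with a median interaction of 1.08 log2 (adjusted p = 0.482 with an estimated correlation, fry adjusted p = 0.0721). RNA from macrophages is argued against: HLA-DRA gives the largest share of any marker, 2.59%, the median over 15 bright markers is -0.07%, and the largest share gives the listed genes a median of -0.0212 against 1.40 observed. RNA quality is argued against as well, because the ACTB 3' minus 5' difference moved by -0.22 between the Hke3 arrays without coculture, which predicts a median of 1.27, and the observed median there is -0.14 (quartiles -0.19 and -0.09). Oxygen or nutrient use in the shared culture and factors from the macrophages remain open and cannot be told apart, since no culture had a second layer of other cells; HCT116 in the same arrangement gave a median of 0.18.

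The cell lines differed in 5364 genes, and their arrays differ in the ACTB 3' minus 5' value by a mean of 0.47 log2. No array of 1 line reaches the values of the other, so a part played by RNA quality cannot be told apart from the cell line.

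The 8 arrays could be split into 4 and 4 in 33 ways that could be fitted. The real split gave 1035 genes for coculture and 5364 for cell line, and the highest other gave 0 for each. Those other splits leave the effect of the real factor in the residual, which lowers their counts, so this comparison does not exclude chance. With all 3 factors kept in the model, which leaves 3 residual degrees of freedom, 1 of the 32 other splits gave 557 and the rest at most 1. The split with 557 follows the interaction of cell line and coculture, which the rest leave at least partly in their error. With a block of the other 2 factors, also with 3 residual degrees of freedom, coculture gave 259 genes and cell line 5131. The cell line count lies above all of those splits, and the coculture count above all but the split by that interaction. The error of these fits holds real interactions, so the comparison does not settle chance. For the interaction of cell line and coculture, 1 of 32 splits, the real one, gave 557 genes, and the highest other gave 1. These splits too hold the real effect in the residual, so they do not exclude chance. With that interaction and the 3 factors in the model, which leaves 2 residual degrees of freedom, the other 31 splits gave at most 9. The count of 557 comes from a fit with 3 residual degrees of freedom and is not directly comparable. In those 31 fits the interaction itself gave 0 to 998 genes, more than the split in 27 and none in 4, so its count there depends on the split added. For vitamin D3 and its interactions with coculture and with cell line the real count is 0, which all 33, 32 and 32 splits reach by construction, so these splits decide nothing. The highest others, 729, 557 and 557, are the split by the interaction of cell line and coculture. This structure of the arrays is the interaction already reported, so these counts restate it and add no support.

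Differences between the lines in the coculture effect, by the interaction test, came to 557 genes. The named genes with the larger value in Hke3 were ANKRD37 (2.12), PFKFB4 (1.75), ANGPTL4 (1.74), SPRY1 (1.53), PPFIA4 (1.45), EGLN3 (1.40), INSIG1 (1.28), DKK1 (1.26) and STARD4 (0.99). Those with the larger value in HCT116 were IL20RB (-2.37), CLGN (-2.16), LURAP1L (-2.12), LAMP3 (-2.02), NRP1 (-2.01), SESN2 (-1.69), DDIT3 (-1.67), CHAC1 (-1.59), TRIB3 (-1.55), GDF15 (-0.99), TWIST1 (-0.98, an approximate size), SLC7A11 (-0.97), HYOU1 (-0.79), HERPUD1 (-0.78), TNFRSF10B (-0.78), DUSP6 (-0.76), SEL1L (-0.72), CDKN1A (-0.65), ESRP1 (-0.57) and SOX9 (-0.51). By camera with the preset correlation the median interaction was 0.375 for cholesterol synthesis, 0.16 for heat shock, -0.789 for ATF4 amino acid response, -0.278 for ER chaperones, -0.188 for p53 targets, -0.067 for RAS-MAPK output and -0.321 for immediate early genes. For coculture and vitamin D3 it was -0.059 for vitamin D receptor targets, 0.362 for hypoxia and glycolysis, 0.245 for RAS-MAPK output, 0.222 for metallothioneins and -0.157 for macrophage markers. None of these lists passed with an estimated correlation.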

How the results depend on the processing

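The model without vitamin D3 labels was added after the data were seen (1456 genes for coculture, 5671 for cell line, 729 for their interaction); all other alternatives were planned. The cause of each change below was not tested unless stated. The coculture count of 1035 stayed within 1.5 times under the 75th percentile filter, mean of probe sets, each probe set on its own, median-centred arrays, cyclic loess, trend and robust fitting, and HCT116 only (1010 to 1317). It was 656 with no filter, which tests more genes, 259 with a block, 75 at 1.5-fold, a stricter call by construction, 224 in Hke3 only, 10 in arrays without vitamin D3 and 0 in those with it (1530 at an unadjusted p under 0.05); these subsets hold 4 arrays and 1 residual degree of freedom. Without each array in turn it ranged from 39 to 435. A similar count did not always mean the same genes. Of the 1043 genes in HCT116 only, 434 were among the 1035, and of the 224 in Hke3 only, 91 were. The other alternatives within 1.5 times shared 688 to 1012 genes with the 1035. The cell line count of 5364 was 10283 for each probe set, 938 at 1.5-fold, 2183 in arrays without vitamin D3 and 1199 in those with it, and ranged from 4142 to 4669 without each array. The interaction of cell line and coculture, 557, was 277 with no filter, 973 at the 75th percentile, 865 for each probe set, 1169 with trend and robust fitting, and 101 to 282 without each array. Vitamin D3 gave 1 gene in arrays without coculture and 0 under every other alternative. Its interaction with coculture gave 2 genes with the mean of probe sets, 10 with all two-way interactions and 0 to 1 without each array, and its interaction with cell line gave 0 throughout. The correlation of vitamin D3 differences between lines was 0.278 in pairs with coculture against 0.164. THP1 genes over 2-fold numbered 183 to 289. All 27 list results that passed by camera, of 132, lost their call with an estimated correlation, and with the mean of probe sets 2 lost and 5 gained one.

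Across the alternatives, genes named for coculture lost their call in 434 cases and kept their side of the threshold in 763; for the interaction of cell line and coculture these were 79 and 486, and for cell line 4 and 1073. Of THP1 differences 12 moved and 44 did not. Reversals of named genes were limited to always-named genes that had missed the threshold. For coculture, VDR was -0.0535 in Hke3 only, -0.0494 in arrays without vitamin D3 and -0.0621 to 0.0914 without each array. CYP24A1 was 1.02 in arrays without vitamin D3 and -0.72 to 0.098 without each array, and SNAI1 -0.0034 in Hke3 only and -0.0561 in arrays with vitamin D3. For vitamin D3, VDR was -0.0372 with the mean of probe sets and -0.0116 in arrays without coculture, SNAI1 0.0357 there, and CYP24A1 -1.17 in arrays with coculture and -0.247 to 0.573 without each array. For cell line, VDR was 0.041 in arrays without coculture, 0.0058 in arrays with vitamin D3 and -0.147 to 0.0225 without each array, and SNAI1 -0.0762 with median-centred arrays, -0.0272 in arrays with coculture and -0.021 to 0.0581 without each array. For coculture and vitamin D3, VDR was -0.0192 with the mean of probe sets and -0.0339 to 0.375 without each array, and AXIN2 -0.17 to 0.0634. Without each array the interaction of cell line and coculture was -0.381 to 0.023 for VDR and -0.524 to 1.47 for CYP24A1, and that of cell line and vitamin D3 was -0.117 to 0.334 for VDR, -1.28 to 0.909 for CYP24A1, -0.0814 to 0.124 for SNAI1 and -0.0192 to 0.192 for AXIN2. Genes under 6.18 log2 on all 8 arrays were tested only with no filter, where 637 of the 656 genes for coculture were among the 1035.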

Other observations

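The remaining lists in THP1 cells treated with vitamin D3 carry no test either. ER chaperones had a median of 0.18 log2 (percentile 98.5 of the random lists) with DNAJC3 at 0.74 and XBP1 at -0.61, and p53 targets had 0.18 (percentile 99.1). RAS-MAPK output had 0.14 (percentile 97.6), with the ERK phosphatase DUSP6 at 0.92 and the growth factor HBEGF at 0.67. NRF2 targets had 0.23 (percentile 98.7), where HMOX1, which breaks down haem, stood at 1.17 and NQO1 at 0.77 while AKR1C1 was lower. Cholesterol synthesis (0.09), heat shock (0.01, although HSPB1 was at -0.80), epithelial genes (0.05), Wnt and beta-catenin targets (-0.04), hypoxia and glycolysis (-0.01) and myeloid surface receptors (-0.02) lay between the 5th and 95th percentile. In that last list CD14 was higher by 5.47 and the complement receptor-related CD93 by 0.88, and the Fc receptor FCGR2A was lower (-0.70).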
